A study of Mus musculus with 9 samples.

How the data were processed

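Seq-Well single-cell RNA sequencing was done by the authors on whole left knee joints of 9 female 129/Sve mice: 4 injected with buffered saline (healthy) and 5 with methylated bovine serum albumin after sensitization to it (sick), taken 1 week after the injection at 8 weeks of age. Per the labels, reads were demultiplexed with bcl2fastq, processed with Picard and the Drop-seq protocol, aligned with STAR, and merged over several sequencing rounds. The labels name 3 builds: the human GRCh38 in one place and the mouse builds GRCm38 and mm9 in another. The gene symbols are those of the mouse, and 22894 of 24296 (94.2%) stand in the GENCODE M21 annotation of GRCm38, from which the coordinates of named genes were taken by symbol. The deposited file holds raw counts of 24296 genes in 16751 cells, and all its values were checked to be whole and not negative. The deposited cells already had at least 397 counts and 199 genes and at most 19.9% mitochondrial counts, and each deposited gene had a count in at least 3 cells. Raw reads were not used here.

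Cells with at least 200 genes and at most 20% mitochondrial counts were kept, and Scrublet was run per mouse. It called 35 cells (0.209%) doublets, so few that the caller has not worked here. The 16714 kept cells (4522 healthy, 12192 sick) were scaled to 10000 counts, log-transformed and clustered (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1, seed 0) with scanpy 1.11.5 and leidenalg 0.10.2. The 19 clusters were named by their leading genes against 24 fixed marker classes, which gave 13 classes and 13991 named cells. A cluster was left unnamed where 3 or more of its leading genes were ribosomal RNA-like or mitochondrially encoded. The same held with fewer than 3 markers, with more leading genes of another class than of its own, or with low counts and no leading marker. A second clustering left out the 156 genes called in any comparison; it put 82.8% of the cells in the same class and left 3318 unnamed.

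Counts were summed per mouse over all kept cells (whole joint) and within each class that had at least 20 cells per mouse in at least 3 mice of each group. Groups were compared on these 4 and 5 sums (3 and 5 for plasmacytoid dendritic cells), with the mouse as the unit, by edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test, R 4.3.3). P-values were adjusted by Benjamini-Hochberg over the tested genes of each comparison at a false discovery rate of 0.05. CPM values are TMM-scaled except where stated, and log2 CPM values carry a prior count of 2. Of 35 fixed gene lists, those with at least 4 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01. They were tested again with an estimated correlation and with fry. Adjustment was over the lists in the whole joint, and separately over all lists and cell classes together. Shares of cells and values per mouse were compared by exact permutation of the 9 mice (126 splits, smallest two-sided p 0.0159). An interaction term tested whether effects differed between neutrophils and erythroid cells. The 10 largest rises and falls in the whole joint, the 5 largest in each class and in the interaction (mean of at least 50 CPM in the higher group and no overlap of the groups, where called), and up to 4 members of each list with the smallest p were named by a rule, from which 2 genes were left out of the text; the lists, markers, comparisons and this rule were fixed before the data were examined.

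Library totals ran from 884249 to 4675477 counts in the whole joint. Within classes they were 36430 to 317780 in B cells, 180499 to 1231444 in erythroid cells, 56699 to 562793 in granulocyte progenitors, 51538 to 965411 in monocytes or macrophages, 59727 to 1149245 in neutrophils and 27575 to 155996 in plasmacytoid dendritic cells. The tests were tested on simulated data with 200 changed genes: 60% of 2-fold and 97% of 4-fold changes were called in the whole joint, against 37% and 88% in monocytes or macrophages and 43% and 80% in plasmacytoid dendritic cells. A gene with no healthy counts is given as a lower bound against a floor of 3 counts over the group, and a gene with 1 to 3 as a ratio of sums with a 95% counting interval. Alternatives tried were DESeq2 1.42.0 (test and size factors), no filter on low counts, each mouse left out, the replicate number as a term, all deposited cells, cells with at least 400 genes, doublets kept, other clustering resolutions and cell minimums, other denominators for shares, counts thinned to 884249 per mouse, and further ones chosen after the data were seen. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. Coordinates on a build other than GRCm38, splicing and sequence variants were not analysed here.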

Results

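Single cells from whole left knee joints of 9 female 129/Sve mice were profiled with Seq-Well, a method that captures the polyadenylated RNA of single cells on barcoded beads in small wells. In the 5 sick mice (numbered 1, 3, 4, 5 and 6) an arthritis had been triggered by a knee injection of methylated bovine serum albumin after sensitization to it, and the 4 healthy mice (numbered 1 to 4) had received buffered saline. The mice were 8 weeks old and were sampled 1 week after the injection. Of the 16751 cells (24296 genes) 16714 were kept. Kept counts per mouse were 1508174, 884249, 1388419 and 1334083 in healthy mice 1 to 4. In sick mice 1, 3, 4, 5 and 6 they were 2424774, 4675477, 1589079, 2824834 and 3201678. The labels give no sequencing batch for a mouse, so no within-batch value could be computed, and a batch that followed the groups could not be told apart from them.

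The first comparison asked whether the groups differed in cell yield and RNA content, since every other value has to be read beside this. Sick joints gave 2438 ± 901 kept cells (SD, n = 5) against 1130.5 ± 226 (n = 4) in healthy joints. The difference had an exact permutation p of 0.0159, which is the smallest p that the 126 splits of the mice allow. Mitochondrially encoded genes took 7.81% ± 2.08 of the counts in healthy mice and 4.00% ± 1.21 in sick mice (exact permutation p = 0.0317). Both p-values became 0.0635 when adjusted over the 4 measures, so neither passed. Without healthy mouse 1 kept cells, the mitochondrial percent and the median number of detected genes all passed (adjusted p = 0.0476 each). The median count per cell was 898 ± 104 in healthy and 892 ± 54.1 in sick mice (exact permutation p = 0.873). The median number of detected genes was 312 ± 60.4 and 370.2 ± 13.4 (exact permutation p = 0.0952, adjusted p = 0.127). Haemoglobin genes took 32.5% ± 10.1 of the counts in healthy and 19.7% ± 6.85 in sick mice (exact permutation p = 0.0635), and transcripts of ribosomal RNA type took 4.83% ± 2.12 and 1.67% ± 0.611 (exact permutation p = 0.0159). These last measures were added after the data were seen.

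The next comparison asked which cell classes differed in their share of the joint. The 19 clusters held marrow and blood cells above all: 4322 neutrophils, 3664 erythroid cells, 2157 monocytes or macrophages, 1235 B cells of an early stage with the surrogate light chain genes Vpreb1 and Igll1, 808 granulocyte progenitors and 657 plasmacytoid dendritic cells. Smaller classes were 348 eosinophils, 182 T or NK cells, 146 skeletal muscle cells, 145 fibroblasts with the lubricin gene Prg4, 118 osteoblasts, 115 plasma cells and 94 mast cells or basophils. One further cluster of 2723 cells was left unnamed, because transcripts of ribosomal RNA type and mitochondrially encoded genes led it. It held 45.0% ± 26.9 (SD, n = 4) of the cells of healthy mice and 5.33% ± 2.18 (n = 5) of those of sick mice. The shares were 5.16% in healthy mouse 1 and 52.4%, 62.6% and 59.7% in healthy mice 2, 3 and 4.

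None of the 13 class shares passed the exact permutation test after adjustment (lowest adjusted p = 0.0884, 7 classes at an unadjusted p under 0.05). Since leading genes of some clusters were themselves called as changed, shares of neutrophils, erythroid cells, plasmacytoid dendritic cells and fibroblasts are given from a second clustering without the 156 called genes, chosen after the data were seen. Neutrophils were 37.1% ± 6.08 of sick (n = 5) and 16.4% ± 12.995 of healthy cells (n = 4), at an exact permutation p of 0.0476. Fibroblasts were 0.972% ± 0.709 and 0.166% ± 0.160 (exact permutation p = 0.0317). Plasmacytoid dendritic cells were 4.15% ± 0.967 and 2.23% ± 1.01 (exact permutation p = 0.0476). Erythroid cells were 13.8% ± 3.59 and 11.3% ± 1.78 (exact permutation p = 0.286), and none of these passed after adjustment (lowest adjusted p = 0.143). The left-out genes included the erythroid markers Hba-a1, Hba-a2, Hbb-bt and Car2. In every mouse the second clustering held fewer erythroid cells and more neutrophils than the first. In sick mouse 6 these were 408 against 829 erythroid cells and 877 against 679 neutrophils, so cells may have moved between these classes. The first clustering gave 25.1% ± 6.46 of sick and 15.5% ± 2.88 of healthy cells for erythroid cells (exact permutation p = 0.0476), 30.3% ± 6.17 and 13.3% ± 13.1 for neutrophils (p = 0.0635), 0.988% ± 0.747 and 0.142% ± 0.119 for fibroblasts (p = 0.0159) and 4.63% ± 1.05 and 2.45% ± 1.28 for plasmacytoid dendritic cells (p = 0.0476). In the first clustering T or NK cells were 1.21% ± 0.195 of sick and 0.804% ± 0.228 of healthy cells (exact permutation p = 0.0476), but 1.30% ± 0.170 and 1.27% ± 0.140 in the second (exact permutation p = 0.762). Mast cells or basophils were 0.660% ± 0.160 and 0.223% ± 0.256 (exact permutation p = 0.0476). For the other classes the means of sick and healthy mice were 8.27% ± 2.25 and 5.88% ± 2.39 for B cells, 5.28% ± 1.80 and 3.68% ± 0.739 for granulocyte progenitors, 14.1% ± 4.68 and 8.06% ± 5.91 for monocytes or macrophages. They were 0.536% ± 0.356 and 0.966% ± 1.00 for osteoblasts and 1.18% ± 0.904 and 0.207% ± 0.202 for skeletal muscle cells. The second clustering gave 1.41% ± 1.08 and 0.975% ± 0.962 for skeletal muscle cells (exact permutation p = 0.556). Eosinophils were 1.83% ± 1.01 of sick and 3.46% ± 4.27 of healthy cells in the second clustering (exact permutation p = 0.698), with 9.85% in healthy mouse 1, and 1.67% ± 0.735 and 3.64% ± 3.85 in the first (p = 0.413). With named cells only in the denominator, an alternative chosen after the data were seen, the difference (sick minus healthy) turned to -4.22 percentage points in erythroid cells, -3.06 in B cells, -0.308 in T or NK cells and -1.76 in granulocyte progenitors, and with the unnamed cluster counted as erythroid that in erythroid cells was -30.0. Other differences could still shrink. Of the named cells of the first clustering, plasmacytoid dendritic cells were 2.67% to 6.33% in healthy and 3.78% to 6.60% in sick mice. Monocytes or macrophages were 11.7% to 17.8% and 9.06% to 21.6%. Both groups thus covered much the same range. Plasma cell shares are not compared, because called genes defined that cluster. Without healthy mice 2, 3 and 4 the difference turned to -2.82 percentage points in monocytes or macrophages and -2.14 in neutrophils.

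**Figure D1:**
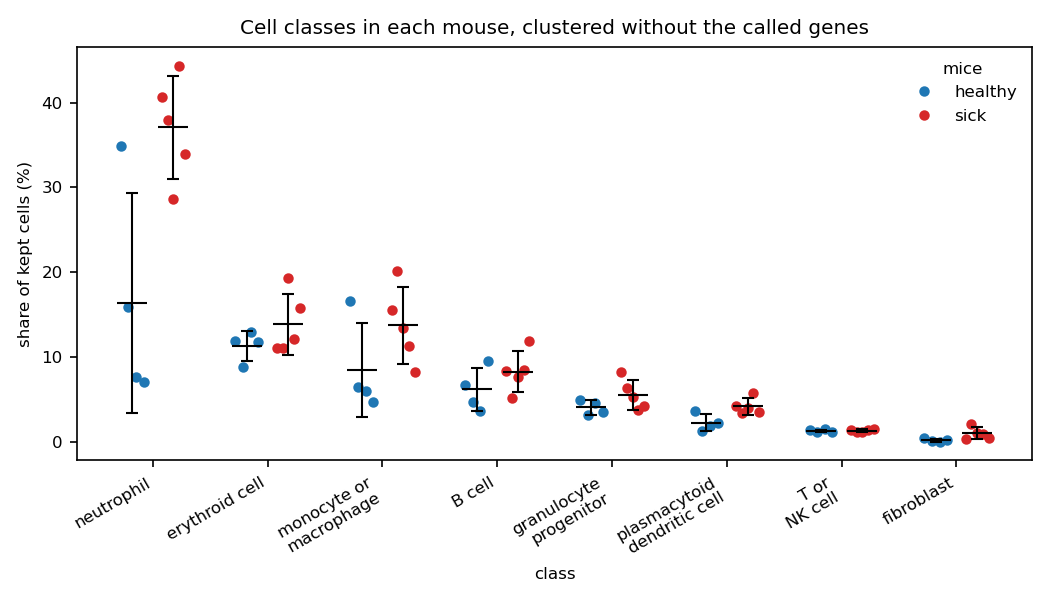
Share of kept cells (percent, vertical axis) of 8 classes in each of 4 healthy (blue) and 5 sick (red) mice, from the clustering without the called genes, with black lines for the mean and bars for the SD over mice. Neutrophils were 34.9% of healthy mouse 1, 15.9%, 7.60% and 7.07% of healthy mice 2, 3 and 4, and 28.6% to 44.4% of the sick mice.

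A further comparison asked which genes differed between the whole joints of sick and healthy mice. Genes that cells switch on in response to interferon rose in the sick joints. Rtp4, a receptor transporter induced by interferon, rose by 4.63 ± 0.35 on the log2 scale (SE, n = 4 and 5), from a mean of 2.25 ± 2.33 CPM to 70.0 ± 11.7 CPM (SD). Ifi27l2a, an interferon-induced gene, rose by 3.16 ± 0.25, Irf7, a transcription factor of the interferon response, by 2.99 ± 0.30. Xaf1, a gene linked to cell death, rose by 2.87 ± 0.25, and Isg15, a ubiquitin-like modifier, by 2.66 ± 0.29. Ifi27 (2.01 ± 0.26) and Slfn4 of the schlafen family (1.75 ± 0.30) also rose, each in 5 of 5 sick mice above every healthy mouse. Oas1a, a sensor of double-stranded RNA, rose by 5.27 ± 0.48 from 4 healthy counts, but it is nearly identical to Oas1g, so its identity is uncertain. By symbol, in an annotation of the GRCm38 build and not in the deposited file, Rtp4 lies on chromosome 16 from 23520291 to 23614222, and Ifi27l2a on chromosome 12 from 103442167 to 103443680, close to Ifi27 at 103434211 to 103440239.

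Of the 23 tested interferon-stimulated genes of a fixed list, 14 rose, none fell and 9 did not pass, and 17 rose when adjusted over the list alone. The list passed camera (adjusted p = 2.53e-63), and it kept its call at an adjusted p = 0.00105 with an estimated correlation, the only one of the 30 lists tested in the whole joint to do so. Mean log2 CPM of the list was 3.13 to 3.33 in the healthy mice and 4.90 to 5.37 in the sick mice. No single left-out mouse ended the call of a gene named here. Without healthy mice 2, 3 and 4, whose cells lay mostly in the unnamed cluster, a fit that assumes the lone healthy mouse varies like the sick ones called 5 of 24 members, while their median log2 fold was 1.99 (1.47 with all mice) and the list passed camera (adjusted p = 1.72e-41).

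**Figure D2:**
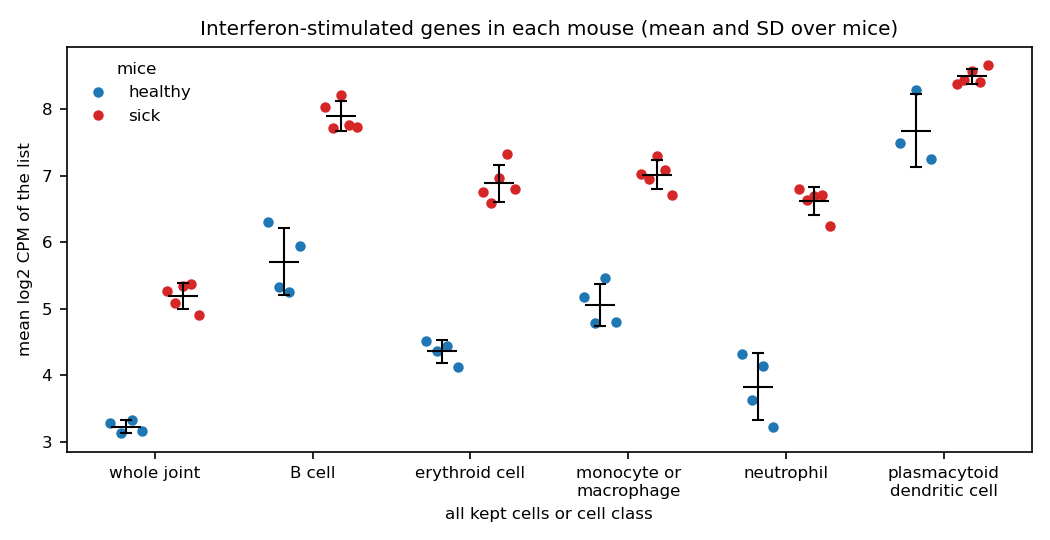
Mean log2 CPM of the interferon-stimulated genes (vertical axis) in the whole joint and in 5 cell classes, for each healthy (blue) and sick (red) mouse, with the mean (line) and SD (bars) over mice. In the whole joint healthy mice lay between 3.13 and 3.33 and sick mice between 4.90 and 5.37.

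Mitochondrially encoded genes of the respiratory chain fell in the whole joints of sick mice. The complex I genes mt-Nd5 (-1.71 ± 0.27, SE), mt-Nd2 (-1.71 ± 0.29), mt-Nd4 (-1.63 ± 0.27), mt-Nd6 (-1.54 ± 0.28) and mt-Nd1 (-1.51 ± 0.27) fell. So did mt-Cytb of complex III (-1.55 ± 0.28) and mt-Co1 of complex IV (-1.28 ± 0.23). In mt-Nd5 the mean went from 654 ± 335 CPM (SD, n = 4) to 199 ± 22.8 CPM (n = 5), below every healthy mouse in 5 of 5 sick mice. Of 9 tested genes of the list 8 fell (9 adjusted over the list alone), with a camera adjusted p of 5.84e-23 and an adjusted p = 0.123 with an estimated correlation. Gm42418, a transcript of ribosomal RNA type, also fell (-1.86 ± 0.36), and so did the haemoglobin pseudogene Hba-ps4 (-1.68 ± 0.33). Both have near-identical copies, so their identity is uncertain. The list's mean log2 CPM was 9.48 in healthy mouse 1 and 10.19, 10.83 and 11.22 in healthy mice 2, 3 and 4, against 8.82 to 9.22 in the sick mice. Without healthy mice 2, 3 and 4 edgeR called none of 10 members, at a median fold of -0.40 and a camera adjusted p of 0.000364. Single mice ended the call of mt-Nd6 (adjusted p = 0.0571 without healthy mouse 4). That of Gm42418 ended (up to 0.0808) without healthy mouse 3 or 4 or sick mouse 3, 5 or 6, and that of Hba-ps4 (up to 0.118, without healthy mouse 2 or 4 or sick mouse 3 or 5).

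**Figure D3:**
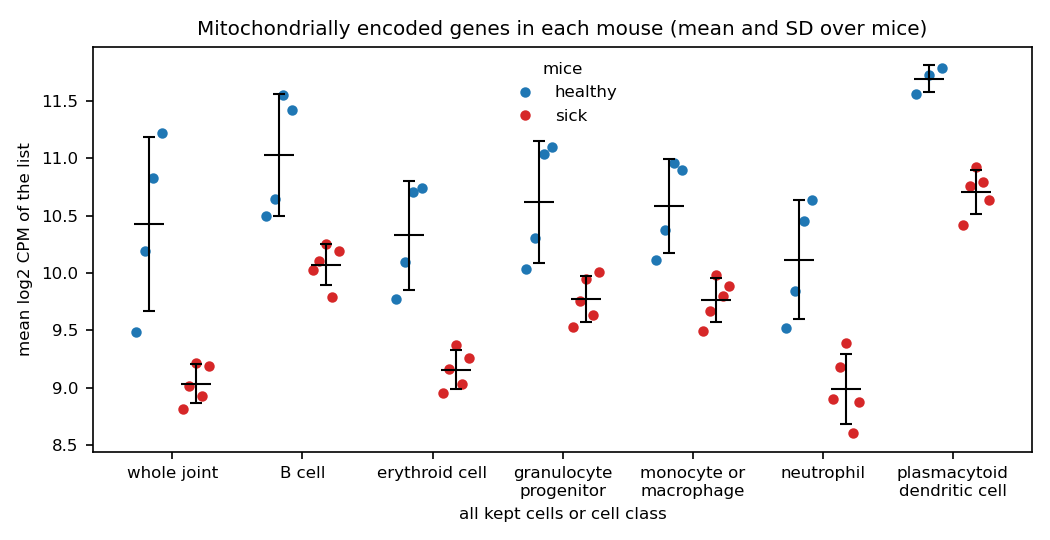
Mean log2 CPM of the mitochondrially encoded genes (vertical axis) in the whole joint and in 6 cell classes, for each healthy (blue) and sick (red) mouse, with the mean (line) and SD (bars) over mice. In the whole joint healthy mouse 1 lay at 9.48, the other healthy mice at 10.19 to 11.22 and the sick mice at 8.82 to 9.22.

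Antibody genes of the IgG type rose in the sick joints. Ighg1 rose by 6.95 ± 0.60 on the log2 scale (SE), from 4.30 ± 3.56 CPM (SD, n = 4) to 503 ± 284 CPM (n = 5), Ighg2b by 3.12 ± 0.59 and Ighg2c by 3.11 ± 0.68. These constant region genes are near-identical and differ between strains and the reference genome, so their split among the 3 genes is uncertain. Plasma cells of 2 sick mice averaged 43916 CPM of Ighg1 without TMM scaling, but since these genes define the cluster, the number of plasma cells was not compared between the groups. Of 11 tested plasma cell and immunoglobulin genes these 3 rose (5 adjusted over the list alone), at a camera adjusted p of 8.08e-11 and an adjusted p = 0.153 with an estimated correlation. Ribonuclease genes of eosinophils fell, with Ear6 at -2.22 ± 0.32 and Ear2 at -1.67 ± 0.29, while eosinophils were 9.85% of the cells of healthy mouse 1, 1.07% to 1.62% of healthy mice 2, 3 and 4 and 0.706% to 3.29% of the sick mice in the second clustering. Ms4a1, the B cell surface antigen that rituximab binds, fell (-1.77 ± 0.30). It alone changed among 18 tested targets of arthritis drugs (1 fell adjusted over the list alone, 5 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.285). It was also the only one called of 6 mature B cell genes (2 adjusted over the list alone). That list was lower at a camera adjusted p of 0.00167 and an adjusted p = 0.279 with an estimated correlation, and its member Ighd stood at -1.60 ± 0.45 (adjusted p = 0.122). The mature B cell list turned to higher without healthy mice 2, 3 and 4 (0.940). Ighg2b lost its call without healthy mouse 2 or 4 (adjusted p up to 0.0790). Ighg2c lost it without healthy mouse 2 or 4 or sick mouse 1, 3 or 5 (up to 0.165).

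**Figure D4:**
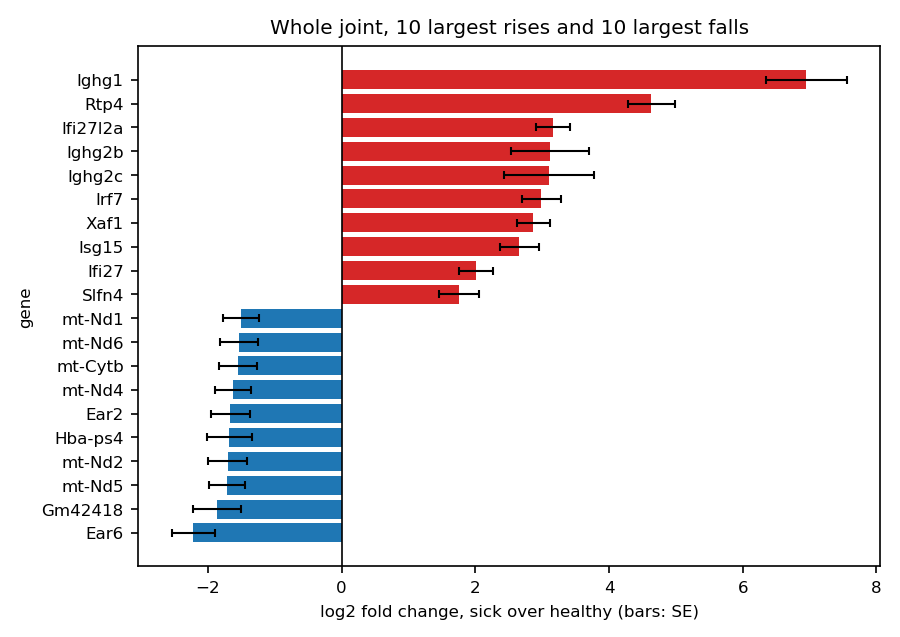
Log2 fold changes, sick over healthy (horizontal axis), of the 10 largest rises (red) and the 10 largest falls (blue) in the whole joint that the naming rule chose, with bars for the SE (n = 4 and 5). Ighg1 stands at 6.95, Rtp4 at 4.63 and Ear6 at -2.22.

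Inflammatory genes were higher in the sick joints as groups, while few passed one by one. Among 15 tested cytokines and chemokines the monocyte attractant Ccl7 rose by 4.51 ± 0.92 (SE, adjusted p = 0.0259), and 5 rose when adjusted over the list alone. Osteopontin (Spp1, 1.94 ± 0.45, adjusted p = 0.0564), Ccl2 (1.20 ± 0.34, adjusted p = 0.122) and the interleukin-1 antagonist Il1rn (1.19 ± 0.34, adjusted p = 0.122) did not pass. That list passed camera at an adjusted p of 3.22e-07 (adjusted p = 0.159 with an estimated correlation). Heat-shock chaperones Hspa1b (5.31 ± 1.05) and Hspa1a (5.47 ± 1.12), known to respond to tissue dissociation too, were the 2 of 16 dissociation and immediate-early genes that rose (6 rose and 1 fell adjusted over the list alone). That list had a camera adjusted p of 1.36e-05 and an adjusted p = 0.159 with an estimated correlation. Its member Dnajb1 was at 1.57 ± 0.37 (adjusted p = 0.0609). Leaving out 1 mouse ended the calls of Ccl7 (adjusted p up to 0.118, without healthy mouse 1, 2, 3 or 4). It also ended those of Hspa1b (up to 0.105, without healthy mouse 2, 3 or 4) and Hspa1a (up to 0.110, without healthy mouse 2, 3 or 4). It brought in Spp1 (0.000378 without sick mouse 1) and Dnajb1 (0.00504 without sick mouse 1 and 0.0353 without sick mouse 4).

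Neutrophil products formed another such group. Of 12 tested S100 alarmins and acute-phase genes none passed over all genes, 8 rose adjusted over the list alone and 9 were higher at an unadjusted p under 0.05. S100a8, which encodes a calcium-binding alarmin, was at 40719 ± 6628 CPM (SD, n = 4) in healthy and 69279 ± 10479.7 CPM (n = 5) in sick mice (0.77 on the log2 scale, adjusted p = 0.186). The list passed camera (adjusted p = 2.13e-08; adjusted p = 0.240 with an estimated correlation). Secondary and tertiary granule genes were higher as a list (4 of 10 adjusted over the list alone, camera adjusted p = 3.35e-06, adjusted p = 0.327 with an estimated correlation). In it were the antimicrobial protein gene Ngp at 0.67 (adjusted p = 0.229), Lcn2, which encodes an iron-siderophore binder, at 0.64 (0.236) and Cd177, a neutrophil surface protein, at 0.92 (0.122). The granule list turned to lower without healthy mice 2, 3 and 4 (adjusted p = 0.940). In the second clustering neutrophils were 34.9% of healthy mouse 1, 7.07% to 15.9% of healthy mice 2, 3 and 4 and 28.6% to 44.4% of the sick mice. Primary granule genes were higher too (1 of 8 adjusted over the list alone, camera adjusted p = 0.0199, adjusted p = 0.472 with an estimated correlation). The lectin gene Fcnb was at 0.66 (0.0845). Leaving out healthy mouse 1 gave calls for Cd177 (adjusted p = 0.00590) and Fcnb (0.0408). Pglyrp1, a peptidoglycan-binding protein gene, went from 0.137 with all mice to 0.0472 without healthy mouse 1 and 0.0297 without sick mouse 4. The primary granule list was lost without healthy mouse 4 (0.242), sick mouse 1 (0.125) or sick mouse 3 (0.0693).

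Other lists that were higher in the sick joints by camera, with no member called over all genes by edgeR, were these. Matrix-degrading enzymes and inhibitors (6 of 10 adjusted over the list alone, 7 at an unadjusted p under 0.05) had an adjusted p of 1.13e-06 and an adjusted p = 0.159 with an estimated correlation. In this list the urokinase receptor Plaur was at 0.80 ± 0.18 (SE, adjusted p = 0.0548), the protease Ctsl at 1.32 ± 0.36 (0.109) and the inhibitor Timp2 at 1.09 ± 0.32 (0.140). Fc receptors (3 of 4 adjusted over the list alone, camera adjusted p = 0.000209, adjusted p = 0.159 with an estimated correlation) included Fcgr4 at 1.84 ± 0.48 (0.0953). Complement genes (3 of 6, camera adjusted p = 0.00203, adjusted p = 0.159 with an estimated correlation) included the anaphylatoxin receptor C5ar1 at 0.82 ± 0.25 (0.143). Glycolysis genes (2 of 18, camera adjusted p = 0.000303, adjusted p = 0.395 with an estimated correlation) included the hexokinase Hk2 at 0.87 ± 0.22 (0.0845) and Ldha at 0.63 ± 0.17 (0.109). Fibrillar collagens and matrix genes (2 of 10, camera adjusted p = 0.00137, adjusted p = 0.336 with an estimated correlation) included Col3a1 at 4.00 ± 0.98 (0.0766) and Fbn1 at 2.51 ± 0.67 (0.106). Nuclear-encoded respiratory chain genes (0 of 24 adjusted over the list alone, 6 higher and 1 lower at an unadjusted p under 0.05, camera adjusted p = 0.00167, adjusted p = 0.247 with an estimated correlation) included Uqcrc1 at 0.46 ± 0.13 (0.132). Inflammatory monocyte genes (1 of 10, camera adjusted p = 0.00291, adjusted p = 0.336 with an estimated correlation) included Plac8 at 0.59 (0.148) and Chil3 at 0.64 (0.238). Unfolded protein response genes (1 of 12, camera adjusted p = 0.0203, adjusted p = 0.399 with an estimated correlation) included Xbp1 at 0.62 (0.122) and the chaperone Hspa5 at 0.33 (0.322). Without healthy mouse 1 Plaur (0.00478), C5ar1 (0.0360), Hk2 (0.0225) and Ldha (0.0458) passed. Plaur (0.0393) and Col3a1 (0.0308) passed without sick mouse 4, and Col3a1 (0.0357) without sick mouse 6. The monocyte list was lost without healthy mouse 4 (0.0554), and the unfolded protein list without healthy mouse 4 (0.148) or sick mouse 3 (0.0552).

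Lower in the sick joints as lists were haemoglobin and erythroid genes (5 of 15 adjusted over the list alone, 9 at an unadjusted p under 0.05, camera adjusted p = 6.29e-07, adjusted p = 0.336 with an estimated correlation). So were G2 and M phase genes (none of 17, camera adjusted p = 0.0319, adjusted p = 0.560 with an estimated correlation). Haemoglobin genes Hba-a2 (-1.31 ± 0.42, SE) and Hbb-bt (-1.13 ± 0.37), which have near-identical copies, did not pass (adjusted p = 0.179 for both). Neither did Cenpf, a mitotic gene, at -0.33 ± 0.16 (0.387). Without healthy mouse 1 Hba-a2 (0.0228) and Hbb-bt (0.0302) passed, while without healthy mice 2, 3 and 4 they turned to 0.44 and 0.13 and their list to higher (0.447). The G2 and M list was lost without healthy mouse 3 (0.325), healthy mouse 4 (0.283), sick mouse 3 (0.111) or sick mouse 5 (0.114).

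For 10 more lists camera gave no call: NF-kB target genes (adjusted p = 0.0556, with Tnfaip2 at 0.57 ± 0.14), pro-B and pre-B cell genes (0.0956, with Dntt of antigen receptor joining at -0.88 ± 0.29), bone formation (0.136), skeletal muscle (0.227) and T cell genes (0.279). The others were hypoxia-responsive (0.470), resident macrophage (0.687), bone resorption (0.687), S phase (0.687) and MHC class II presentation genes (0.775). NF-kB genes passed without healthy mouse 1 (0.00771), sick mouse 1 (0.00256) or sick mouse 4 (0.0351). Bone formation passed without healthy mouse 3 (0.00289), sick mouse 1 (0.0113) or sick mouse 5 (0.0163). T cell genes passed without healthy mouse 1 (0.0314) and muscle genes without sick mouse 1 (8.05e-05). Pro-B and pre-B cell genes passed without healthy mouse 1 (0.0377), 2 (0.0245) or 3 (0.0122) or sick mouse 5 (0.0363) or 6 (0.0223). In the NF-kB list Tnfaip2 passed without healthy mouse 1 (0.0395). Cartilage matrix, cytotoxic and NK cell, endothelial, platelet and keratinocyte lists had fewer than 4 tested genes and were not tested as lists.

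Over the whole joint edgeR's quasi-likelihood test called 94 of 10311 genes at a Benjamini-Hochberg false discovery rate of 0.05, of which 63 rose and 31 fell. In 495 of the 10311 tested genes (4.80%) the values of the groups did not overlap, where chance gives 1.59%. The count was 237 without healthy mouse 1, 60 without healthy mouse 2, 62 without healthy mouse 4, 60 without sick mouse 3 and 52 without sick mouse 5. With other settings it was 249 (DESeq2's Wald test), 284 (no filter on low counts), 53 (at least 400 genes per cell) and 60 (without the unnamed cluster, 49 higher and 11 lower). It was 12, of which 8 were among the 94, without healthy mice 2, 3 and 4.

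The comparisons within cell classes asked whether the same differences were present inside a class, apart from the mixture of cells. The haemoglobin gene Hbb-bs had a count in nearly all cells of every class tested. Changes of haemoglobin genes outside erythroid cells were thus not told apart from free RNA released by red cells. In neutrophils interferon-stimulated genes rose. Ifi27l2a rose by 4.01 ± 0.40 on the log2 scale (SE), from 13.2 ± 16.9 CPM (SD, n = 4) to 368 ± 83.4 CPM (n = 5), and Rtp4 by 4.20 ± 0.51. Isg15 had 2 healthy counts and a ratio of 36.2 (95% counting interval 9.98 to 300.2). Oas1a, with no healthy counts, was at least 11.2-fold higher against a floor of 3 counts over the group. Of 11 tested list members 7 rose (8 adjusted over the list alone), at a camera adjusted p of 2.72e-27 and an adjusted p = 0.0174 with an estimated correlation. Antibody genes Igkc (1.58 ± 0.29) and Ighg1 (ratio 81.2, interval 14.5 to 3214, from 1 healthy count) rose as well, in a class not known to make antibody. Their list (2 of 6 rose) had a camera adjusted p of 8.40e-05 and an adjusted p = 0.166 with an estimated correlation. Without TMM scaling, Ighg1 averaged 109 CPM in the neutrophils of sick mice, 122 in B cells, 141 in erythroid cells and 43916 in plasma cells.

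In the same neutrophils mt-Nd5 (-1.38 ± 0.27, SE), mt-Nd2 (-1.25 ± 0.28), mt-Cytb (-1.22 ± 0.25), mt-Nd1 (-1.11 ± 0.23) and mt-Nd4 (-0.99 ± 0.23) fell. Without the immature neutrophil cluster none of the 6 falls of this class kept its call: 8 of 1567 genes were called there, all higher. In that fit mt-Nd5 was at -1.27 ± 0.36 (adjusted p = 0.153), mt-Nd2 at -1.33 ± 0.37 (0.141), mt-Cytb at -1.14 ± 0.30 (0.108), mt-Nd1 at -0.99 ± 0.31 (0.228) and mt-Nd4 at -0.33 ± 0.32 (0.778), and Igkc, at 1.36 ± 0.34, lost its call too. Of 9 tested mitochondrially encoded genes 6 fell (9 adjusted over the list alone), with a camera adjusted p of 3.37e-22 and an adjusted p = 0.0675 with an estimated correlation. S100 alarmins (camera adjusted p = 0.0163, adjusted p = 0.482 with an estimated correlation; S100a8 at 0.50 ± 0.21, adjusted p = 0.399) were higher as a list with no member called. So were matrix-degrading enzymes (0.0329; 0.343 with an estimated correlation; Ctss at 1.47 ± 0.53), cytokines (0.0181; 0.307 with an estimated correlation; Spp1 at 0.94 ± 0.43) and nuclear-encoded respiratory chain genes (0.000365; 0.166 with an estimated correlation). Haemoglobin genes were lower (6.53e-05; 0.343 with an estimated correlation; Hbb-bt at -0.71 ± 0.26). That list turned to higher (0.00436), Hbb-bt to 0.43 and the cytokine list to lower (0.999) without healthy mice 2, 3 and 4. The test called 19 of 3877 genes, of which 13 rose and 6 fell. That count was 54 without healthy mouse 1, 33 without sick mouse 4, 11 without sick mouse 5, and 11 without healthy mice 2, 3 and 4. Without 1 mouse mt-Nd5 (adjusted p up to 0.104, healthy 3 or 4), mt-Cytb (0.139, healthy 3 or 4 or sick 5), mt-Nd1 (0.196, healthy 3 or 4 or sick 5 or 6), mt-Nd2 (0.247, healthy 3 or 4 or sick 1, 5 or 6) and mt-Nd4 (0.218, healthy 2, 3 or 4 or sick 1, 5 or 6) lost their calls. S100a8 (0.0311) and Hbb-bt (0.0206) gained one without healthy 1. The S100 (up to 0.0691, sick 3, 5 or 6), matrix (0.198, healthy 4 or sick 3 or 5), cytokine (0.110, healthy 4 or sick 5) and haemoglobin lists (0.0592, healthy 3) were lost.

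Erythroid cells of sick mice carried more interferon-stimulated RNA and less mitochondrially encoded RNA. The class joined 3 clusters, and Isg15 was among their leading genes. The largest held 108 to 148 cells per healthy mouse and 178 to 490 per sick mouse. Another held 10 to 27 and 86 to 267, so changes within the class were not told apart from this mix of clusters. Isg15 rose by 3.13 ± 0.30 on the log2 scale (SE), from 31.6 ± 10.8 CPM (SD, n = 4) to 297 ± 93.4 CPM (n = 5), Irf7 by 4.04 ± 0.48 and Ifi27l2a by 3.45 ± 0.42. Rtp4, with 2 healthy counts, had a ratio of 27.1 (interval 7.44 to 225). Of 8 tested list members 5 rose (8 adjusted over the list alone), at a camera adjusted p of 1.08e-32 and an adjusted p = 0.0174 with an estimated correlation. The mitochondrial genes mt-Nd2 (-1.43 ± 0.20), mt-Cytb (-1.38 ± 0.20), mt-Nd5 (-1.31 ± 0.21), mt-Nd4 (-1.21 ± 0.20) and mt-Co1 (-1.12 ± 0.20) fell. In this list 7 of 8 members were called (8 adjusted over the list alone), at a camera adjusted p of 8.94e-29 and an adjusted p = 0.0387 with an estimated correlation. Neutrophil products rose too, with Pglyrp1 by 1.19 ± 0.26 and Lcn2 by 0.84 ± 0.20, in a class not known to make granules. S100a6, a member of the S100 list and not a fixed neutrophil marker, rose by 1.15 ± 0.28. S100 alarmins (3 of 10 rose, 9 adjusted over the list alone; camera adjusted p = 6.11e-13, adjusted p = 0.133 with an estimated correlation) were higher as a list. So were secondary and tertiary granule genes (1 of 9 rose, 9 adjusted over the list alone; camera adjusted p = 8.94e-11, adjusted p = 0.147 with an estimated correlation). Without TMM scaling S100a8 averaged 18352 ± 3233 CPM (SD) in healthy and 36643 ± 4010.0 CPM in sick erythroid cells, against 132420 ± 27327 CPM and 181985 ± 13109 CPM in neutrophils.

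Chaperone genes also rose in erythroid cells: Hspa1b, with no healthy counts, was at least 31.1-fold higher, and Dnajb1 rose by 1.64 ± 0.39 (SE). Their dissociation and immediate-early list (2 of 15 rose; 4 rose and 1 fell adjusted over the list alone) passed camera (adjusted p = 0.000446; adjusted p = 0.166 with an estimated correlation). Ighg1 had a ratio of 76.8 (interval 21.2 to 636) from 2 healthy counts, and its list was higher (1 of 7; camera adjusted p = 0.0163, adjusted p = 0.395 with an estimated correlation). Cytokines (0.000430; 0.147 with an estimated correlation; Spp1 at 2.87 ± 0.76, adjusted p = 0.0784) were higher as a list with no member called. So were glycolysis (0.000566; 0.106 with an estimated correlation), nuclear-encoded respiratory chain (0.00999; 0.166) and matrix-degrading genes (0.0220; 0.388; Plaur at 0.81 ± 0.25). Haemoglobin and erythroid genes were lower (0.0276; 0.535 with an estimated correlation). In all 42 of 4640 genes were called, of which 32 rose and 10 fell. The count was 27 without healthy mouse 1, 20 without sick mouse 5, 28 without healthy mouse 4 or sick mouse 3, and 4 without healthy mice 2, 3 and 4. Calls ended without 1 mouse for Pglyrp1 (adjusted p up to 0.0907, healthy 1 or 4 or sick 5 or 6), S100a6 (0.175, all but sick 1 and 4) and Lcn2 (0.150, healthy 1, 3 or 4 or sick 3, 5 or 6). They also ended for Dnajb1 (0.139, all but sick 1 and 4) and Hspa1b (0.109, each healthy mouse). Lists lost were those of cytokines (0.0825, healthy 4), matrix-degrading (0.259, healthy 1 or 4 or sick 3), plasma cell (0.131, healthy 1 or 4) and haemoglobin genes (0.290, healthy 3 or sick 1, 3 or 4). Spp1 passed without sick 1 (0.00461).

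Monocytes or macrophages of sick mice also had more interferon-stimulated RNA. Ifi27l2a rose by 2.63 ± 0.28 on the log2 scale (SE), to 941 CPM from 128 CPM (n = 5 and 4), Xaf1 by 2.80 ± 0.42 and Ifi44 by 3.00 ± 0.49. Rtp4 (ratio 15.3, interval 4.15 to 127) and Oas1a (ratio 28.2, interval 4.98 to 1124) had 2 and 1 healthy counts. Of 14 tested list members 9 rose (11 adjusted over the list alone), at a camera adjusted p of 9.84e-24 and an adjusted p = 0.0196 with an estimated correlation. The complement gene C1qb, a marker of tissue macrophages, rose by 3.75 ± 0.76, and the chaperone Hsph1 by 4.03 ± 0.89. Sick mouse 3 held 245 of the 493 cells of the cluster that C1q genes led. The mitochondrial genes mt-Nd2 (-0.99 ± 0.22) and mt-Nd5 (-0.87 ± 0.20) fell, together with CT010467.1, annotated as ribosomal RNA (-1.10 ± 0.21). Of the 9 mitochondrially encoded genes only mt-Nd2 and mt-Nd5 were called (9 adjusted over the list alone; camera adjusted p = 4.52e-14, adjusted p = 0.0867 with an estimated correlation). Ighg1 had a ratio of 78.9 (interval 14.1 to 3124) from 1 healthy count. Its list was higher (1 of 4; camera adjusted p = 0.00110, adjusted p = 0.188 with an estimated correlation), as was complement (1 of 6; 0.00901, and 0.227 with an estimated correlation).

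With no member called, lists higher in this class were S100 alarmins (camera adjusted p = 1.36e-06, adjusted p = 0.166 with an estimated correlation; S100a8 at 0.95 ± 0.28), granule genes (5.17e-05; 0.166; Ngp at 0.85 ± 0.24) and dissociation genes (0.000271; 0.0675; Hspa1a at 4.30 ± 1.03). Others were matrix-degrading genes (0.000659; 0.166; Ctsl at 1.50 ± 0.48), nuclear-encoded respiratory chain (0.00144; 0.0867) and unfolded protein response (0.00234; 0.225). Glycolysis (0.0310; 0.233; Aldoa at 0.85 ± 0.26) and cytokines (0.0363; 0.343; Spp1 at 2.47 ± 0.77) followed, each second value being the adjusted p with an estimated correlation. Haemoglobin genes were lower (0.0460, and an adjusted p = 0.629 with an estimated correlation), but turned to higher without healthy mice 2, 3 and 4 (1.22e-05). The test called 28 of 4468 genes, of which 23 rose and 5 fell. Without healthy mouse 1 it called 19, of which 8 rose and 11 fell. Without 1 mouse the count was 9 (healthy 2), 13 (healthy 3), 15 (healthy 4), 47 (sick 1), 10 (sick 3) or 9 (sick 5), and it was 4 without healthy mice 2, 3 and 4. Calls ended for C1qb (adjusted p up to 0.0998), Hsph1 (0.156) and Ighg1 (0.204) without each healthy mouse, and for Ifi44 (0.0599), Rtp4 (0.0521) and Oas1a (0.121) without healthy 1. They also ended for mt-Nd2 (0.197, all but healthy 1 and sick 1 and 4), mt-Nd5 (0.187, all but healthy 1 and sick 1 and 6) and CT010467.1 (0.0901, healthy 2 or 3 or sick 3 or 5). Lists lost were those of complement (0.116, healthy 1 or sick 3 or 5), glycolysis (0.0860, healthy 2, 3 or 4 or sick 3 or 5), cytokine (0.167, sick 3 or 5) and haemoglobin genes (0.827, healthy 2, 3 or 4 or sick 1, 3 or 5). Without sick mouse 1 Hspa1a (4.21e-05), Spp1 (0.00744) and Ctsl (0.0233) passed, and without healthy mouse 4 S100a8 (0.0103) and Ngp (0.0469).

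B cells of sick mice carried more of the interferon-induced genes Ifi27l2a (3.78 ± 0.44 on the log2 scale, SE), Ifitm3 (2.09 ± 0.33) and Slfn4 (2.39 ± 0.48), all of which rose. The mean of Ifi27l2a went from 35.6 ± 33.0 CPM (SD, n = 4) to 622 ± 217 CPM (n = 5), and Isg15, with 2 healthy counts, had a ratio of 11.6 (interval 3.13 to 97.0). Of 4 tested interferon-stimulated genes 2 rose (3 adjusted over the list alone), at a camera adjusted p of 2.00e-08 and an adjusted p = 0.0174 with an estimated correlation. Xaf1 was at 2.28 ± 0.63 (adjusted p = 0.0516). The chaperone Hsph1 rose by 3.05 ± 0.71. Among genes of red cells the carbonic anhydrase Car2 fell (-1.17 ± 0.24). So did Hba-a2 (-1.38 ± 0.35), Hbb-bt (-1.27 ± 0.33) and Hba-ps4 (-1.89 ± 0.26), the last 3 with near-identical copies. Of 11 haemoglobin and erythroid genes 4 fell (11 adjusted over the list alone; camera adjusted p = 2.26e-16, adjusted p = 0.106 with an estimated correlation). Without TMM scaling Hbb-bs averaged 169697 ± 41718 CPM (SD) in healthy and 102836 ± 38500 CPM in sick B cells. It had a count in 100% of them, so less free RNA of red cells could not be told apart from a fall inside B cells. Fam213a (-2.45 ± 0.38), the ethanolamine kinase Etnk1 (-1.60 ± 0.41) and Mir6236, whose locus catches ribosomal RNA (-1.87 ± 0.28), fell too.

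In B cells 7 of 9 mitochondrially encoded genes fell (8 adjusted over the list alone; camera adjusted p = 4.38e-17, adjusted p = 0.0754 with an estimated correlation). Among them were mt-Nd4 (-1.64 ± 0.26, SE), mt-Cytb (-1.15 ± 0.23) and mt-Nd5 (-1.10 ± 0.22). Nuclear-encoded respiratory chain genes (camera adjusted p = 0.00880, adjusted p = 0.107 with an estimated correlation; Uqcrq at 0.86 ± 0.25, adjusted p = 0.0753) were higher as a list with no member called. So were inflammatory monocyte genes (0.0122; 0.227 with an estimated correlation). In B cells S100 alarmins (camera adjusted p = 0.0619, adjusted p = 0.571 with an estimated correlation) and secondary and tertiary granule genes (0.667, and 0.912 with an estimated correlation) did not pass, with no member called over all genes or over the list alone. Without TMM scaling S100a8 averaged 24447 ± 10778 CPM (SD) in healthy and 39646 ± 7553 CPM in sick B cells, and S100a9 10744 ± 4248 CPM and 17030.3 ± 3182 CPM. The test called 32 of 1869 genes, of which 9 rose and 23 fell. With no filter on low counts 44 rose and 6 fell, and with clustering resolution 0.5 there were 9 rises and 8 falls. The count was 15 without healthy mouse 3 or 4, 16 without sick mouse 3 or 5, and 8 without healthy mice 2, 3 and 4. Calls ended for Isg15 (adjusted p = 0.110), mt-Cytb (0.112), Hsph1 (0.0530) and the monocyte list (0.152) without healthy 4. They ended for mt-Nd5 (up to 0.0627) without healthy 3 or 4, for Car2 (0.0613) without healthy 3 or sick 3, for Etnk1 (0.177) without each healthy mouse or sick 3 or 5. The same held for Hba-a2 (0.190) and Hbb-bt (0.237) without healthy 3 or 4 or sick 1, 3, 4 or 5. Xaf1 passed without sick 6 (0.0120).

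In granulocyte progenitors, the precursors of neutrophils, genes of later neutrophil granules rose. Chil3, a chitinase-like protein gene, rose by 1.20 ± 0.21 on the log2 scale (SE), Pglyrp1 by 1.31 ± 0.24, Ngp by 1.15 ± 0.21, the cathelicidin gene Camp by 1.08 ± 0.22 and Lcn2 by 1.02 ± 0.20. Further rises were those of the alarmin S100a9 by 1.01 ± 0.23, Cd177 by 1.07 ± 0.28 and Fcnb by 0.77 ± 0.18 (n = 4 and 5). S100 alarmins (5 of 10 rose, 8 adjusted over the list alone; camera adjusted p = 2.30e-14, adjusted p = 0.0754 with an estimated correlation) were higher as a list. So were secondary and tertiary granule genes (4 of 9, 8 adjusted over the list alone; 2.55e-12, and 0.0675 with an estimated correlation) and primary granule genes (1 of 8; 0.0271, and 0.400 with an estimated correlation). Over 17 S100 and granule genes tested in both classes the log2 folds exceeded those in erythroid cells by a median of 0.116, and none differed by more than 2 SE. That SE treats the 2 folds as independent although the same mice gave both, so smaller differences may be missed. Ifi27l2a (3.09 ± 0.74), Ifi27 (2.56 ± 0.49) and Ifitm3 (1.45 ± 0.27) of the interferon response rose. So did the protease Ctss (2.09 ± 0.51) and Ubqln1 of protein quality control (1.64 ± 0.39). The histone gene Hist1h1a (-1.95 ± 0.37), the histone chaperone Asf1a (-1.12 ± 0.26) and the stem cell surface protein Cd93 (-1.53 ± 0.33) fell, with Ccdc50 (-1.16 ± 0.30) and the pseudogene Gm6548 (-1.43 ± 0.36). The fixed lists of S phase genes (camera adjusted p = 0.372, none of 15 called) and G2 and M phase genes (0.947, none of 13 called) did not pass in this class. The haemoglobin genes Hba-a2 (-1.67 ± 0.32) and Hba-a1 (-1.55 ± 0.30) and the mitochondrial mt-Rnr1 (-1.14 ± 0.25) and mt-Nd1 (-0.83 ± 0.22) fell.

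Chaperones rose in the progenitors, with Hsp90aa1 at 1.07 ± 0.26 (SE), Hspa1b at a ratio of 32.4 (interval 8.89 to 269) from 2 healthy counts and Hspa1a at 54.2 (interval 9.64 to 2150.0) from 1. The lists of dissociation genes (3 of 15 rose; camera adjusted p = 0.00123, adjusted p = 0.106 with an estimated correlation), matrix-degrading genes (1 of 4; 0.0310, and 0.216 with an estimated correlation) and nuclear-encoded respiratory chain genes (no member; 0.0195, and 0.148 with an estimated correlation) were higher. Lower were those of mitochondrially encoded (2 of 8 fell; 1.36e-11, and 0.104 with an estimated correlation) and haemoglobin genes (3 of 11 fell; 1.31e-07, and 0.166 with an estimated correlation). The test called 42 of 2993 genes, of which 30 rose and 12 fell. The count was 24 without healthy mouse 4, 26 without sick mouse 5 or 6, and 10 without healthy mice 2, 3 and 4, where Hba-a1 turned to 0.57, Hba-a2 to 0.86 and their list to higher (0.771). Calls ended for S100a9 (adjusted p up to 0.0675) and Fcnb (0.0624) without healthy 4 or sick 6, Cd177 (0.317, healthy 1 or 4 or sick 3, 5 or 6), Ifi27l2a (0.105, healthy 1 or 4), Ctss (0.0715, healthy 4) and Ubqln1 (0.0532, healthy 1 or 3). They ended for Hist1h1a (0.0550, healthy 1), Asf1a (0.0731, healthy 2 or 3), Ccdc50 (0.216, all but healthy 3 and sick 1) and Gm6548 (0.233, healthy 1, 2 or 3 or sick 1 or 3). The same held for Hba-a1 (0.0526, healthy 3), mt-Rnr1 (0.0702, healthy 3) and mt-Nd1 (0.236, healthy 3 or 4 or sick 1, 5 or 6). Among chaperones it held for Hsp90aa1 (0.0994, healthy 1, 2 or 4 or sick 5 or 6), Hspa1b (0.0699, healthy 1) and Hspa1a (0.0911, healthy 1 or 4). Among the lists, primary granule (0.259, healthy 4 or sick 3 or 6), dissociation (0.146, sick 3 or 5), matrix-degrading (0.332, healthy 1 or 4) and nuclear-encoded respiratory chain genes (0.110, healthy 2) were lost.

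In plasmacytoid dendritic cells, known as producers of type I interferon, 4 of 1380 genes were called with 3 healthy and 5 sick mice. Ifi27l2a rose by 2.75 ± 0.55 on the log2 scale (SE), from 71.8 ± 65.5 CPM (SD, n = 3) to 515 ± 163 CPM (n = 5), and Cyba, a subunit of the oxidase that makes superoxide, by 1.82 ± 0.39. Both mt-Cytb (-1.21 ± 0.22) and Mir6236 (-1.61 ± 0.32) fell. Among 8 mitochondrially encoded genes 1 fell (8 adjusted over the list alone; camera adjusted p = 2.30e-14, adjusted p = 0.0196 with an estimated correlation), with mt-Nd4 at -1.17 ± 0.28 (adjusted p = 0.0873). The interferon list rose in 1 of 4 genes (1 adjusted over the list alone; camera adjusted p = 0.0287, adjusted p = 0.166 with an estimated correlation). Bst2, an antiviral surface protein gene, was at 0.48 ± 0.30. S100 alarmins (1.07e-06; adjusted p = 0.150 with an estimated correlation; S100a9 at 1.05 ± 0.30) and granule genes (0.000180; 0.201 with an estimated correlation; Ltf at 1.41 ± 0.36, Camp at 1.08 ± 0.27) were higher as lists with no member called. Lower were G2 and M phase genes (0.00109; 0.166 with an estimated correlation; Mki67 at -1.10 ± 0.26, adjusted p = 0.0761) and haemoglobin genes (0.00187; 0.400 with an estimated correlation; higher without healthy mice 2, 3 and 4, 0.0581). The count was 2 without healthy 3 or sick 6, 0 without healthy 4, 8 without sick 1 and 16 without sick 4. It was 0 by edgeR without healthy mice 2, 3 and 4 (300 of 3426 genes at an unadjusted p under 0.05). Calls ended for Ifi27l2a (adjusted p up to 0.104, healthy 1 or 4), Cyba (0.177, each healthy mouse or sick 3, 5 or 6), mt-Cytb (0.220, healthy 1 or 4), Mir6236 (0.126, healthy 3 or 4 or sick 5 or 6) and the haemoglobin list (0.149, healthy 3 or 4 or sick 1). They began for Ltf (0.00167), Camp (0.0115) and S100a9 (0.0395) without sick 4, Mki67 (up to 0.0395, healthy 1 or sick 1 or 4) and mt-Nd4 (0.0328, sick 5).

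A test of the difference itself asked whether arthritis went with other changes in erythroid cells than in neutrophils, the 2 largest classes tested. None of 5644 genes had an interaction that passed edgeR's test in the 9 mice, with 414 at an unadjusted p under 0.05 and 2 passing with DESeq2's size factors. Among the largest estimates the sick-to-healthy change was higher in erythroid cells by 4.74 ± 2.12 (log2, SE) for Hspa1b (adjusted p = 0.606), 4.10 ± 0.99 for Entpd1, an enzyme that breaks down extracellular ATP (0.109), 3.38 ± 1.07 for Tmem216 (0.277). It was higher by 3.21 ± 0.80 for Gm14548 (0.119) and 2.91 ± 0.83 for Calcrl (0.224). It was lower in erythroid cells by -4.50 ± 2.11 for Nrip1 (0.623), -4.26 ± 2.17 for Tom1l1 (0.677) and -4.06 ± 3.07 for Oas1a (0.877). It was also lower by -3.07 ± 1.09 for Brpf3 (0.383). Most of these genes had almost no counts in one of the 4 class and group combinations, so the fitted sizes are no bounds. With 1 mouse left out the estimate ran from 0.976 to 5.17 for Hspa1b and from 3.45 to 6.50 for Entpd1. It ran from -5.09 to -1.67 for Oas1a and from -6.22 to -1.76 for Brpf3. The count was 6 without healthy mouse 2 or 3, 8 without sick mouse 1 and 15 without healthy mice 2, 3 and 4. Among named genes Entpd1 (down to 0.0295) and Gm14548 (0.0395, both healthy 3 or sick 1) passed without 1 mouse.

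The series title speaks of individual treatment, so the spread between mice of a group was also measured. Log2 CPM correlated across genes at a median Pearson r of 0.938 between sick mice and 0.891 between healthy mice, where genes are not independent replicates. Among sick mice interferon-stimulated genes spread from 4.90 in mouse 6 to 5.37 in mouse 5 (mean log2 CPM). Cytokines and chemokines spread from 4.90 in mouse 1 to 5.93 in mouse 3. Fibrillar collagens and matrix genes spread from 4.48 in mouse 5 to 6.69 in mouse 3, and skeletal muscle genes from 2.63 in mouse 1 to 6.54 in mouse 4. Hspa1b was near absent in sick mouse 1 (1.35 CPM) and reached 80.0, 80.7, 248 and 202 CPM in sick mice 3, 4, 5 and 6. Fibroblasts were 85 of the 3849 cells of sick mouse 3 and 7 of the 2092 cells of sick mouse 1.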

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

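Of the tests in this part, only the thinning of the libraries was written down before its result was seen; all others, including the counts of other splits, were chosen after the result was seen.

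Across 408 groups of values, 35 (8.58%) held a mouse whose gap to its nearest neighbour took more of the group's range than Dixon's 95% critical value allows, where chance gives about 1 in 20. Healthy mouse 1 had a median of 402 genes per cell, 9.37% eosinophils and 16.9% monocytes or macrophages, and healthy mouse 3 had 0.502% plasma cells. In mean log2 CPM of lists over the whole joint, healthy mouse 1 stood apart in NF-kB target genes (4.98), healthy mouse 2 in bone resorption genes (3.80), healthy mouse 3 in complement genes (5.25) and sick mouse 4 in glycolysis genes (4.56). In log2 CPM of single genes over the whole joint, healthy mouse 1 stood apart in Rtp4 (2.73) and Plaur (7.94), sick mouse 5 in Slfn4 (8.66), sick mouse 4 in Pglyrp1 (7.83) and Cd177 (7.90), and sick mouse 1 in Fcnb (10.25) and Hspa1b (1.16).

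Within classes single mice stood apart in log2 CPM as follows. In B cells these were healthy mouse 1 in Isg15 (5.64) and healthy mouse 3 in Car2 (11.92), and in erythroid cells healthy mouse 1 in Ighg1 (3.26) and Rtp4 (3.26), sick mouse 5 in Rtp4 (6.81) and healthy mouse 2 in Irf7 (1.89). In granulocyte progenitors they were sick mouse 6 in Ctss (6.05), healthy mouse 4 in Gm6548 (6.71), sick mouse 5 in Asf1a (6.77), healthy mouse 1 in Chil3 (9.07) and healthy mouse 3 in Hspa1a (5.13). In monocytes or macrophages they were healthy mouse 1 in Ighg1 (3.50), Oas1a (3.50) and Rtp4 (3.91) and healthy mouse 4 in S100a8 (14.88). In neutrophils they were healthy mouse 1 in Ighg1 (2.92) and Rtp4 (4.04), healthy mouse 2 in Isg15 (4.70) and sick mouse 6 in Isg15 (5.93), and in plasmacytoid dendritic cells sick mouse 4 in Ltf (9.15). Where the other healthy mice had no count of a gene, 1 or 2 counts set a mouse apart. In the cells of the unnamed cluster, which no comparison within a class used, Ifi27l2a without TMM scaling averaged 300.8 ± 136 CPM (SD, n = 5) in sick mice against 17.8 ± 13.02 CPM (n = 4) in healthy mice.

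The first pattern weighed was the rise of interferon-stimulated genes in sick mice. Without the cells of the unnamed cluster 14 members were still called, and after thinning all libraries to the lowest total 13 were, which argues against the unnamed cluster and against depth as the whole cause. Levels made up only of free RNA of 1 class would give all members the same ratio between B cells and erythroid cells. The SD of that log2 ratio over members was 1.35 in the sick mice, from -1.38 for Rsad2 to 3.42 for Ifi204. This ratio used levels in sick mice and not the rise over healthy mice. A class's own level of a member breaks the equal ratio too, so the test cannot decide whether free RNA gave the rise. Without TMM scaling, Isg15 ran over the named classes of sick mice from 14.5 ± 20.5 CPM (SD, n = 2) in osteoblasts to 281 ± 70.2 (n = 5) in erythroid cells. The osteoblast value is near the floor, with a count in a mean of 1.85% of the cells. Isg15 was 43.4 in plasma cells (n = 2), 67.9 in plasmacytoid dendritic cells and 69.0 in granulocyte progenitors. In B cells, fibroblasts, monocytes or macrophages, eosinophils and neutrophils it was 114 to 124. In skeletal muscle cells it was 144, in T or NK cells 149 and in mast cells or basophils 186 (n = 1). Ifi27l2a, also without TMM scaling, was 103 in eosinophils, 117 in granulocyte progenitors and 135 in erythroid cells. It was 335 in neutrophils, 363 in plasmacytoid dendritic cells, 519 in B cells and 856 in monocytes or macrophages. Neither gene stood at 1 level over all classes, but several classes lay close together. Free RNA as a part of each level and as a source of the rise stays open. A response to interferon in this arthritis and a batch that followed the groups both stay open, and neither was tested.

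The second pattern was the higher level of S100 and granule genes in erythroid cells, granulocyte progenitors, monocytes or macrophages and plasmacytoid dendritic cells. In B cells neither list passed (camera adjusted p = 0.0619 for S100 alarmins and 0.667 for granule genes), which decides nothing on free RNA, since S100a8 without TMM scaling averaged 24447 CPM in healthy and 39646 CPM in sick B cells. The log2 ratio of B cell to erythroid cell CPM had an SD of 0.345 over members in sick mice. That of erythroid cells to neutrophils had an SD of 0.794 around a median of -2.34, from -2.77 to 0.337 for S100a10. A member that a class makes itself can widen such an SD. In erythroid cells a rise of their own thus cannot be told apart from free RNA of neutrophils. For granulocyte progenitors to neutrophils the SD was 0.935, with S100a10 highest at 0.875. For plasmacytoid dendritic cells to neutrophils it was 1.34, with S100a10 highest at 2.86. For erythroid cells to monocytes or macrophages it was 1.53, with S100a4 lowest at -5.60. In sick mice S100a8 had a count in 98.9% to 100% of the cells of each class (means over mice). In granulocyte progenitors the folds exceeded those in erythroid cells by a median of 0.116 over 17 genes, higher in 9 of them and by over 2 SE in none. That SE treats the 2 folds as independent although the same mice gave both, so the comparison cannot decide. Free RNA of neutrophils and a rise in the progenitors themselves both stay open there, and doublets with neutrophils were not tested.

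The third pattern was the lower level of mitochondrially encoded genes in sick mice. Without the cells of the unnamed cluster 7 members were still called, which argues against that cluster as the whole cause. Healthy mouse 1, which had few such cells, stood 0.268 (log2) above the highest sick mouse, while the sick mice spanned 0.397, so an effect of arthritis cannot be told apart from 3 healthy libraries that stand apart. What set healthy mice 2, 3 and 4 apart stays open, and no biological explanation was tested.

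Other splits of the mice into groups of the same sizes, 100 drawn of 126, were fitted the same way. For called genes 2 of 100 splits gave as many as the real split in the whole joint (94, highest other 183), 1 in B cells (32, 28), 1 in erythroid cells (42, 19), 1 in granulocyte progenitors (42, 36), 1 in monocytes or macrophages (28, 26) and 2 in neutrophils (19, 46), the real one included. Few splits thus gave as many, which makes chance unlikely as the whole source of these counts but does not exclude it. The highest other split in the whole joint and in neutrophils set healthy mice 2, 3 and 4 with sick mouse 4 against the rest, which points to a structure of the samples. In plasmacytoid dendritic cells 5 of 56 splits gave as many genes (4, 15), so chance cannot be excluded there. For the interaction the real count was 0 by edgeR (414 genes at an unadjusted p under 0.05 and 2 with DESeq2's size factors). Every split reaches a count of 0, so the splits decide nothing on the interaction, and the highest other split gave 6.

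For passing lists 15 of 100 splits gave as many in the whole joint (19, highest other 23), 19 in B cells (5, 8), 10 in erythroid cells (12 when adjusted within the class, 15), 7 in monocytes or macrophages (13, 14) and 12 in neutrophils (8, 11), so chance cannot be excluded for these counts. For granulocyte progenitors 3 of 100 did (8, 8) and for plasmacytoid dendritic cells 1 of 56 (6, 5). So few splits make chance unlikely there but do not exclude it.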

How the results depend on the processing

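The alternatives without healthy mice 2, 3 and 4, without the unnamed cluster, with the highest 5% of doublet scores removed, with the same mice but no replicate number term, without the immature neutrophil cluster, without the macrophage cluster, with named cells only in the denominator, with the unnamed cluster counted as erythroid and with clustering without the called genes were chosen after the data were seen. All others had been set earlier. For every change below the cause was not tested, except where fewer mice, cells or genes were fitted by construction.

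Of the values of named genes, 2502 kept direction and side of the threshold under the others, 307 lost and 123 gained a call, and none reversed. Under added ones 381 kept both, 164 lost and 7 gained a call, and 5 reversed. Of the values of lists 807 kept both under the others, 181 lost and 16 gained a call and 10 reversed, and under added ones 59, 33, 4 and 15. Of the shares 217 kept both under the others, and under added ones 56 kept both and 8 reversed.

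In the whole joint the 94 called genes became 249 with DESeq2's Wald test, 284 with no filter on low counts, 53 with at least 400 genes per cell, 60 without the unnamed cluster, 12 without healthy mice 2, 3 and 4, and 52 to 237 with 1 mouse left out. In B cells the 32 became 50 with no filter, 17 at resolution 0.5, 8 without healthy mice 2, 3 and 4 and 15 to 41 with 1 mouse left out. In erythroid cells the 42 became 190 with no filter, 4 without healthy mice 2, 3 and 4 and 20 to 56 with 1 mouse left out. In granulocyte progenitors the 42 became 85 with no filter, 10 without healthy mice 2, 3 and 4 and 24 to 56 with 1 mouse left out. In monocytes or macrophages the 28 became 120 with no filter, 9 with at least 400 genes, 9 with at least 50 cells per mouse, 4 without healthy mice 2, 3 and 4 and 9 to 47 with 1 mouse left out. In neutrophils the 19 became 69 with no filter, 8 without the immature neutrophil cluster, 11 without healthy mice 2, 3 and 4 and 11 to 54 with 1 mouse left out. In plasmacytoid dendritic cells the 4 became 10 with DESeq2's Wald test, 45 with no filter, 7 with all deposited cells, 2 with the highest 5% of doublet scores removed, 12 with at least 10 cells per mouse, 0 by edgeR without healthy mice 2, 3 and 4 (300 at an unadjusted p under 0.05) and 0 to 16 with 1 mouse left out. The interaction, 0 by edgeR, gave 2 with DESeq2's size factors, 15 without healthy mice 2, 3 and 4 and 0 to 8 with 1 mouse left out.

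Pairing by the replicate number was not shown by the data: the correlations of same-number mice were 0.172, -0.0474 and 0.0692 in the whole joint, so the block on that number is only an alternative. With the block 80 genes were called in the whole joint, 19 in B cells, 44 in erythroid cells, 20 in granulocyte progenitors, 1 in monocytes or macrophages, 21 in neutrophils and 14 in plasmacytoid dendritic cells. With the same mice and no such term there were 25 in the whole joint, 13 in B cells, 22 in erythroid cells, 0 by edgeR in granulocyte progenitors (262 at an unadjusted p under 0.05), 4 in monocytes or macrophages, 10 in neutrophils and 3 in plasmacytoid dendritic cells. With the block the hypoxia list reversed (adjusted p = 0.988).

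Of the lists 19 passed camera in the whole joint, 5 in B cells, 11 in erythroid cells, 8 in granulocyte progenitors, 13 in monocytes or macrophages, 8 in neutrophils and 6 in plasmacytoid dendritic cells. With an estimated correlation 1, 1, 2, 0, 1, 1 and 1 did, and with fry 5, 3, 4, 2, 4, 3 and 1. Without healthy mice 2, 3 and 4 there were 10 in the whole joint, 5 in granulocyte progenitors, 8 in monocytes or macrophages and 4 in neutrophils. With 1 mouse left out there were 4 to 8 in B cells, 5 to 10 in granulocyte progenitors, 8 to 13 in monocytes or macrophages, 5 to 11 in neutrophils and 3 to 7 in plasmacytoid dendritic cells.

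Without healthy mice 2, 3 and 4 these lists reversed in the whole joint: NF-kB target genes (adjusted p = 0.957), secondary and tertiary granule, mature B cell, pro-B and pre-B cell and hypoxia genes (0.940 each), T cell genes (0.121), haemoglobin and erythroid genes (0.447), S phase genes (0.00924) and targets of arthritis drugs (0.562). Haemoglobin and erythroid genes reversed there in granulocyte progenitors (0.771), monocytes or macrophages (1.22e-05), neutrophils (0.00436) and plasmacytoid dendritic cells (0.0581), and cytokines in neutrophils (0.999). MHC class II genes reversed without the unnamed cluster (0.702). With 1 mouse left out adjusted p ran from 0.255 to 0.983 for MHC class II genes, 0.118 to 0.734 for resident macrophage, 0.0122 to 0.973 for pro-B and pre-B cell, 8.05e-05 to 0.787 for muscle and 0.0828 to 0.977 for S phase genes, each reversing in at least 1 case. Of named genes Hba-a2 (0.44) and Hbb-bt (0.13) in the whole joint, Hba-a1 (0.57) and Hba-a2 (0.86) in granulocyte progenitors and Hbb-bt in neutrophils (0.43) reversed without healthy mice 2, 3 and 4.

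With named cells only in the denominator the differences of shares (percentage points) reversed for B cells (-3.06), T or NK cells (-0.308), erythroid cells (-4.22) and granulocyte progenitors (-1.76). With the unnamed cluster counted as erythroid the erythroid difference was -30.0. Without healthy mice 2, 3 and 4 monocytes or macrophages (-2.82), neutrophils (-2.14) and osteoblasts (0.440) reversed. With 1 mouse left out the difference in kept cells ran from 955 to 1568, in median counts from -50.6 to 30.8, in median genes from 44.9 to 88.2 and in mitochondrial percent from -4.59 to -2.98. The median correlation between healthy mice was 0.919 with 2000 genes in place of 0.891.

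The interferon-stimulated list called 14 of 23 members without the unnamed cluster and 13 of 20 after thinning, and 5 of 24 without healthy mice 2, 3 and 4, where its median fold was 1.99. A pseudocount of 0.1 was not run, since the file holds counts. At least 400 genes gave no value in B cells, neutrophils and plasmacytoid dendritic cells, and at least 50 cells per mouse none in B cells, granulocyte progenitors and plasmacytoid dendritic cells. Depth limits the classes more than the whole joint: the lowest library held 27575 counts in plasmacytoid dendritic cells and 884249 in the whole joint, and 1380 and 10311 genes were tested.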
